A study of Homo sapiens with 6 samples.

How the data were processed

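Gene expression was measured on 6 single-colour Agilent microarrays hybridised with Cy3-labelled cRNA from SW480 cells, a human line established from a colorectal carcinoma. Per the labels, 3 arrays carried RNA of cells stably transfected with a control short hairpin RNA (shRNA). The other 3 carried RNA of cells with an shRNA against PIPKIγ, the type I gamma phosphatidylinositol phosphate kinase encoded by PIP5K1C. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

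The values used are the authors' deposited normalized signals on the log2 scale, with 1 value per probe and array. RMA is named, without a version, per the submitters' processing notes; the scanner and the feature extraction software are not given in the sources used here. The log base is not stated by the deposited table. It was taken as log2 because RMA gives log2 values and the highest value, 17.15, lies near the top of a scanner's range. The array medians lay between 3.141 and 3.151, and the sorted columns differed from their mean by at most 0.096, so the arrays had been brought to nearly 1 distribution before deposit. The lowest value was 0.836, and 31.6 to 31.8 percent of the values of an array lay below 1.2, packed just above that floor. How the floor was made is not given in the sources used here. No detection calls were used here, and changes of probes near the floor may be too small or too large. The 2 array control features, dark and bright corner spots, were left out of the tests, which leaves 58201 probes. No scanner files, scan dates or slide numbers were used here, so batches could not be tested. The number of arrays limits the precision.

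Each probe's log2 values were compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block). The p-values were adjusted by the Benjamini-Hochberg method over all 58201 probes, and a probe was called changed at an adjusted p under 0.05. No probe was filtered out. Fold changes are 2 to the power of the difference of the group means, with 95 percent intervals from limma's moderated standard error. The fit was tested on simulated data with the probe means of these 6 arrays and normal noise, independent between probes. The noise had limma's moderated spreads, which are shrunk towards a common value, so the rates below may be too favourable. Among the 58201 probes 200 were changed, all drawn from those with a mean above the median probe. The fit called 95 of 100 simulated 8-fold changes and 60 of 100 simulated 2-fold changes, each with the right sign. It also made 6 false calls, 3.73 percent of all calls. These rates do not cover probes below the median. They also need not hold for the data, where a far larger share of probes, 24.4 percent, was called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

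The table of counts that the authors deposited gives how many features passed 5 combinations of a p threshold and a fold threshold. Its headers call these features genes, while the counts made here are of probes. Neither the test nor which group is the first is stated in that table. Its counts were set beside those of an ordinary two-sample statistic with equal variances, which was planned, and with unequal variances, which was chosen after seeing the data, both computed here from the deposited log2 values.

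The probes were not named to genes. The deposited table holds Agilent probe IDs alone, and no ID matched the reference gene table used here. The planned comparisons by gene, including that of PIP5K1C itself, and the tests of 31 gene lists on glycolysis, hypoxia, growth signalling and other processes were therefore not run. Counts are counts of probes, and several probes can measure 1 gene. The extent of the knockdown was not checked here.

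Before the data were examined, a rule was fixed for the items named in the text. It took the largest rises and falls with an adjusted p under 0.05, no overlap between the groups and a mean over all 6 arrays above the median. After seeing the data, both group means were required to lie above the median probe (2.97), so that the change was measured on both sides, and only 2 probes each way are named. This passed over 2 larger rises, those of ranks 1 and 3. Alternatives to the normalization, the filter on dim probes, the variance model, the array weights, the block, the arrays included and the calling rule were tried, and their effect is given after the results.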

Results

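The study compared the transcripts of SW480 colorectal cancer cells carrying an shRNA against PIPKIγ with those of SW480 cells carrying a control shRNA, with 3 arrays in each group. PIPKIγ makes phosphatidylinositol 4,5-bisphosphate, a membrane lipid that serves as a signal and as a substrate of other signalling enzymes. The title of the study places the comparison in the context of the Warburg effect, the preference of tumour cells for glycolysis in the presence of oxygen. Signals are given on the log2 scale, where a difference of 1 is a 2-fold change. They ran from a floor of 0.836 to 17.15 over 58201 probes. The probes could not be paired with genes here, so the results below are for probes, and the level of PIP5K1C was not analysed here.

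Arrays of 1 group resembled each other more than arrays of different groups. Across probes, Pearson's correlation was 0.9825 to 0.9904 between arrays of the same group and 0.9723 to 0.9803 between arrays of different groups. In a principal component analysis of the 21353 probes with a mean above 5, the first component held 90.8 percent of the variance and separated the groups. On it the control arrays lay at -51.6, -54.3 and -51.5, and the PIPKIγ shRNA arrays at 50.4, 53.8 and 53.1. The second component held 4.23 percent and set control replicate 2, at -22.2, apart from the other arrays, which lay between -3.1 and 12.1.

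The PIPKIγ shRNA cells differed from the control cells at 14172 of 58201 probes, 24.4 percent of those tested (limma, adjusted p under 0.05, 3 arrays against 3). Of these, 6093 probes were higher and 8079 lower in the PIPKIγ shRNA cells as deposited, an order that turned to 7307 higher and 6650 lower under cyclic loess, a scaling chosen after seeing the data. Most of the changes were small. The median change of a called probe was 1.53-fold, 10635 calls (75 percent) were smaller than 2-fold, and 6654 were smaller than 1.5-fold. When a change was required to exceed 1.2-fold by limma's treat test, 7498 probes were called.

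Large changes were mostly rises. At least 2-fold changes were called at 3537 probes, 1874 higher and 1663 lower as deposited, 2155 higher and 1320 lower under cyclic loess, and 1112 higher and 719 lower with an offset of 16 on the linear scale, which damps the changes of dim probes. Among the 697 probes that changed at least 4-fold, 579 rose and 118 fell, and among the 240 that changed at least 8-fold, 231 rose and 9 fell. Without control shRNA replicate 1 the falls of at least 8-fold numbered 18. At least 16-fold rises were called at 117 probes and at least 64-fold rises at 36, with 0 falls of either size by limma at an adjusted p or at an unadjusted p under 0.05. The called rises of at least 8-fold included 76 probes whose control mean was under 2, close to the floor. Where both group means lay above the median probe, as for 27925 probes, changes of at least 8-fold were 132 rises and 2 falls, and changes of at least 64-fold were 21 rises and 0 falls. The offset of 16 left 122 rises and 0 falls of at least 8-fold.

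**Figure D1:**
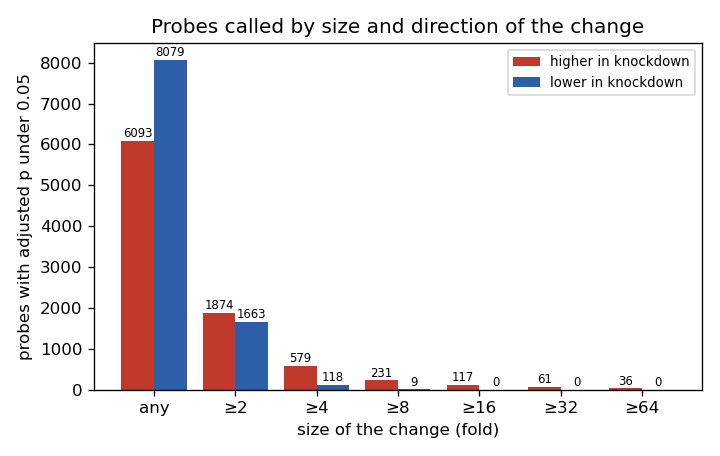
Number of probes called at an adjusted p under 0.05 (vertical axis) that changed by at least the fold given on the horizontal axis, with probes higher in PIPKIγ shRNA cells in red and lower in blue. Lower probes outnumber higher ones over all sizes as deposited (8079 against 6093, but 6650 against 7307 under cyclic loess), while at 8-fold or more 231 probes are higher and 9 lower.

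The 2 named rises were of probes that were dim in the control cells and bright in the PIPKIγ shRNA cells. The probe A_23_P45871 rose from 3.24 ± 0.0855 (SD, n = 3) in control cells to 11.11 ± 0.0238 (n = 3) in PIPKIγ shRNA cells. This is a difference of 7.87 (standard error 0.057, limma adjusted p = 2.24e-06), or 234-fold with a 95 percent interval of 212 to 259 that covers the spread between arrays only. With an offset of 16 on the linear scale the same probe rose 87.5-fold, since its control signal was dim. The probe A_33_P3220911 rose from 4.05 ± 0.157 to 11.59 ± 0.0169 (SD, n = 3 each), 186-fold with an interval of 159 to 217 (limma adjusted p = 6.63e-06), and 95-fold with the offset. In size these were the rises of ranks 2 and 4 among all called probes.

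The largest called fall was much smaller than the largest rises. The probe A_32_P30649 fell from 7.28 ± 0.0319 in control cells to 3.30 ± 0.0822 in PIPKIγ shRNA cells (SD, n = 3 each), a 15.8-fold decrease with an interval of 14.3 to 17.5 (limma adjusted p = 1.05e-05). With the offset of 16 it fell 6.63-fold, since its signal in the PIPKIγ shRNA cells was dim. The next, A_22_P00000924, fell from 8.0 ± 0.07 to 4.35 ± 0.137 (SD, n = 3 each), a 12.6-fold decrease with an interval of 10.8 to 14.7 (limma adjusted p = 4.06e-05), and a 7.49-fold decrease with the offset. These 4 probes were chosen for large called changes and for no overlap between the 3 arrays of either group. That their differences exceeded the spread between replicates therefore follows from the choice and is no added evidence. Chance alone gives groups without overlap at 10 percent of unchanged probes.

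**Figure D2:**
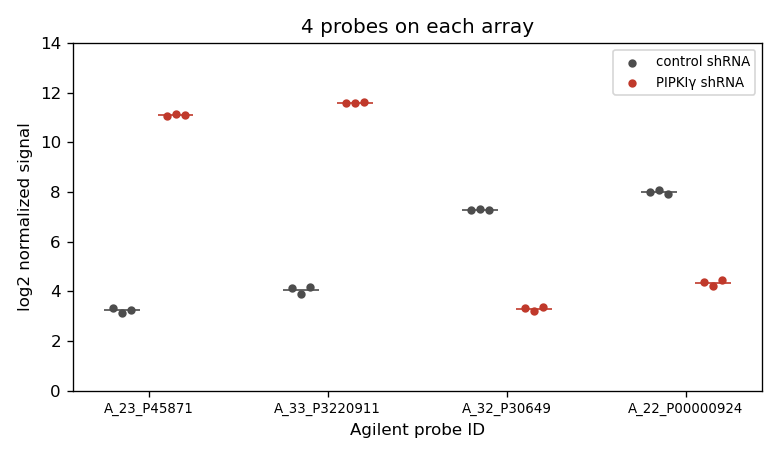
Log2 normalized signal (vertical axis) of 4 probes (horizontal axis) on each of the 6 arrays, with control shRNA arrays in grey, PIPKIγ shRNA arrays in red and a line at each group's mean of 3 arrays. A_23_P45871 and A_33_P3220911 lie near 11.11 and 11.59 in PIPKIγ shRNA cells against 3.24 and 4.05 in control cells, while A_32_P30649 and A_22_P00000924 fall from 7.28 and 8.0 to 3.30 and 4.35.

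Some probes went from near the floor to a clear signal. With no test applied, 19 probes were below 2 on all 3 control arrays and above 5 on all 3 PIPKIγ shRNA arrays, and 0 probes did the opposite.

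The share of probes called depended on their brightness. Of the 24278 probes with a mean of at most 2, 1.78 percent were called. The share was 23.2 percent for means between 3 and 5, 56.6 percent between 7 and 9, 61.5 percent between 11 and 13, and 48.7 percent for the brightest probes, above 13. The median standard deviation within groups was 0.237 for means of at most 2, 0.595 between 2 and 3 and 0.272 between 3 and 5, and was 0.0549 between 11 and 13 and 0.0491 above 13. Rises of at least 8-fold were called in each class above a mean of 2. They numbered 74 for means between 3 and 5, 48 between 5 and 7, 38 between 7 and 9, 33 between 9 and 11, and 17 between 11 and 13. The falls of at least 8-fold all had means below 7.

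**Figure D3:**
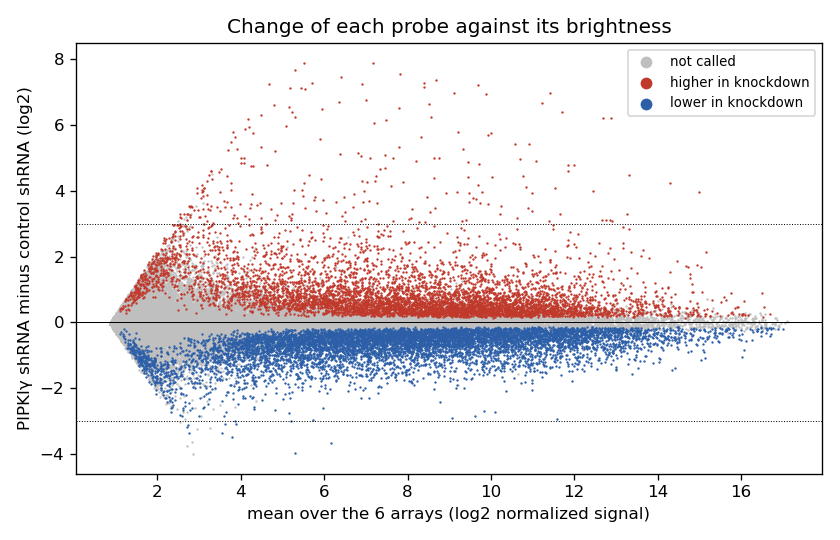
Difference between the mean of 3 PIPKIγ shRNA arrays and the mean of 3 control shRNA arrays (vertical axis, log2) against the mean over the 6 arrays (horizontal axis, log2 normalized signal) for 58201 probes, with called probes in red (higher) or blue (lower), the rest in grey and dotted lines at 8-fold. Points above the upper dotted line, 231 of them called, occur at most levels of brightness, while 9 called points lie below the lower one.

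The authors' deposited table gives 9648 features at a p threshold of 0.01, of which 4238 were up and 5410 down, and 15050 at a threshold of 0.05, of which 6466 were up and 8584 down. With a 2-fold threshold added, the authors' deposited table gives 2415 (1337 up and 1078 down) and 2889 (1570 up and 1319 down). An ordinary two-sample statistic with equal variances, the planned one, gave 12494 and 17962 probes here at the same thresholds without adjustment, and 3090 and 3858 with the 2-fold threshold. With unequal variances, chosen after seeing the data, the counts were 9940 and 16198, and 2607 and 3533 with the 2-fold threshold. The headers of the authors' deposited table call its features genes, so its counts and these counts of probes may differ in unit. The direction of the authors' counts is not stated. The last row of the authors' deposited table adds a limit written as mean7 to the p threshold of 0.05 and the 2-fold threshold, and gives 1576 (907 up and 669 down). This limit was read as a higher group mean above 7, which the table does not state. The count here was then 1602 (927 higher and 675 lower in the PIPKIγ shRNA cells) with equal variances. With unequal variances it was 1584 (913 higher and 671 lower). Both splits lie close to 907 up and 669 down if up means higher in the PIPKIγ shRNA cells, and far from them if it means lower. If up means higher in the PIPKIγ shRNA cells, the share of features up was 43.9 and 43.0 percent in the authors' deposited table and 44.0 and 43.1 percent here with unequal variances, and with the 2-fold threshold 55.4 and 54.3 percent against 55.2 and 52.9 percent. With the opposite reading, 4238 up would stand against 5569 lower here at a p threshold of 0.01. With the 2-fold threshold added, 1337 up would stand against 1169 lower.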

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

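Cyclic loess and the ordinary statistic with unequal variances were chosen after seeing the data. Leaving out 1 array at a time gave 11155 to 12908 changed probes, 4937 to 5714 higher and 6218 to 7202 lower, 3289 to 3693 changed at least 2-fold and 234 to 260 higher at least 8-fold. The share of changed probes that were higher was then 42.3 to 44.5 percent. The 11 other scalings, filters, weights, blocks and variance models left 9477 to 15806 probes changed, and the share higher stayed between 42.4 and 45.3 percent except under cyclic loess, where it turned to 52.4 percent. The quantile, 75th percentile and median scalings could move little, since the arrays already had nearly 1 distribution. The log2 changes of the 4 named probes kept their direction and their call in all 66 such combinations of probe and setting in which the probe was tested, but not their size. With the offset of 16 they were 6.45, 6.57, -2.73 and -2.90, since 1 side of each change is dim. The 4 probes were chosen for large called changes, so that they kept their calls says little about other probes.

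The calling rule moved the counts by its construction. The treat test against 1.2-fold gave 7498 probes (3418 higher, 4080 lower), and adding a 2-fold threshold to the adjusted p gave 3537 (1874 higher, 1663 lower). Unadjusted p under 0.05 with at least 2-fold gave 3858 (2006 higher, 1852 lower) with equal variances and 3533 (1869 higher, 1664 lower) with unequal variances. Testing only probes above the 75th percentile left 1260 changed at least 2-fold and 89 higher at least 8-fold, since fewer probes were tested. The offset of 16 left 1831 and 122, since it shrinks the changes of dim probes.

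With the replicate number as a block, 9477 probes were changed, 4176 higher and 5301 lower, and 9111 of them were also called without it. The numbers did not pair the samples: deviations from the group means of same-numbered arrays correlated at -0.0036, -0.012 and -0.007 (-0.025, -0.043 and 0.13 over probes with a mean above 5), and no control array correlated best with its own number over all probes.

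The analyses by gene (mean or most variable probe) and the set tests were not run, since probes were not named. Few dim probes were called, 1.78 percent of those with a mean of at most 2. Whether the floor or a lack of change accounts for this was not tested.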

Other observations

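The tests of brightness-dependent shifts, whole-array scaling, floor, single arrays and centring below were chosen after the results they bear on were seen. The test of mixed RNA and the splits of the arrays were not.

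The real grouping of the 6 arrays gave 14172 changed probes, and the highest count among the other splits into 3 and 3 was 0 (limma, adjusted p under 0.05), with 1012 to 1637 probes at an unadjusted p under 0.05 against 18896 for the real grouping. Of the 10 splits, 1 gave as many calls, the real one. With 10 splits the share cannot fall under 0.1, so they are too few for a share under 0.05. Each other split also puts arrays of both groups on each side. The difference between the groups then widens the spread and lowers the counts, so these are not the counts that chance alone would give.

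The largest changes were nearly all rises, 231 against 9 at 8-fold or more. After cyclic loess the ratio of rises to falls of this size was 36.7 (257 against 7). That outcome decides little, since the scaling had only small shifts to remove. As deposited, the median change of the brightness classes lay between -0.15 and 0.00654. Medians this small argue against a brightness-dependent shift left in the deposited values as the source of 8-fold changes. They cannot decide on shifts in the raw signals, since the arrays had nearly 1 distribution before deposit. Among 23049 probes whose mean over the 6 arrays left room for an 8-fold change both ways, 151 rose and 2 fell this far (98.7 percent rises). A rise also lifts that mean, so a probe dim in the controls can enter this set. Among 17523 probes whose control mean left such room, 66 rose and 2 fell this far (97.1 percent rises). Both counts argue against falls hidden by the floor. Leaving out each of the 6 arrays in turn gave a ratio of at least 13.2, the lowest without control shRNA replicate 1 (237 against 18). A call needs replicates that agree, so this ratio could hardly fall far. With no test applied, PIPKIγ shRNA replicates 1, 2 and 3 were each set against the control mean. They had 317, 677 and 624 rises of at least 8-fold and 18, 33 and 24 falls. Of these rises, 227, 223 and 225 were among the 231 called ones. A probe at the floor can rise this far on 1 array but cannot fall. These counts therefore cannot decide on 1 deviating PIPKIγ shRNA array. A response to the loss of PIPKIγ, a response to the hairpin or its vector and a difference between the stably transfected populations that arose in selection were not tested, since the labels name 1 hairpin per group and the probes have no gene names.

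Lower calls outnumbered higher ones as deposited, 8079 against 6093, and the median change of all probes with means between 3 and 5 was -0.15 against 0.00191 between 9 and 11. After median centring 43.9 percent of calls were higher, but the centring moved the median change of all probes only from -0.015 to -0.0074, so a constant factor per array stays open. A shift between the arrays that depends on brightness may account for the excess of lower calls, since 52.4 percent of calls were higher after cyclic loess. That method centres the changes at each brightness, so it would also remove a real excess of small falls, and these cannot be told apart. The order of the counts is therefore open, while rises of at least 8-fold outnumbered falls under cyclic loess as well, 257 against 7.

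Control replicate 2 stood apart at some bright probes. Among 9128 probes with a mean above 9, it differed by more than 0.5 on the log2 scale from both other controls' mean at 215 probes where those 2 arrays lay within 0.2 of each other, and it was the lower one at 210 of them. The same count was 3 to 34 on the other 5 arrays. Scaling of the whole array would move the bright probes together, and their median difference was 0.015 in the deposited values, against -0.858 at the 215 probes. The arrays had nearly 1 distribution before deposit, so the first median would lie near 0 in any case. It therefore cannot decide on the scaling of the raw signals. Against mixed-in PIPKIγ shRNA RNA, the PIPKIγ shRNA mean lay at least as far out at 6.98 percent of the 215 probes. A local defect of the array surface and a difference between cultures were not tested, since spot positions were not used here. Without this array 12908 probes were called, the highest of the 6 counts with 1 array left out, which began at 11155.

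The share of called probes within 1 window of brightness, a mean between 7 and 9, ranged over the 7 probe ID series from 51.2 percent of 420 probes to 64.5 percent of 265 probes. What the series of IDs stand for is not given in the sources used here.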
